A study of Mus musculus with 6 samples.

How the data were processed

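Gene expression was measured in neural stem cells, multipotent progenitors that grow in culture under mitogens, taken from the brains of C57BL6 mice at postnatal day 0. Cells carried 3 genotypes of Ecrg4, a gene for a small secreted protein, and 2 arrays were labelled with each genotype. The cells were kept in DMEM/F12 with bFGF, EGF and heparin and had no treatment, per the labels. Total RNA was isolated on RNeasy columns and amplified to amino allyl aRNA, and a dye was coupled by the array maker's protocol, per the labels' protocols. The same labels give biotin as the label, and this disagreement is left open. How the Ecrg4 allele was changed, and whether replicates came from separate animals or cultures, is not given in the sources used here. All p-values therefore measure only the spread between these arrays, which may be technical.

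The authors deposited 1-colour intensity values on a linear scale, and the table of these values was the starting point. Each column's median over its measured probes was 30, so the values were read as scaled to a common median by the authors. Background correction, the scanner and the rule that leaves a cell blank are not given in the sources used here, and scanner files were not used here. The table held 23466 probes, of which between 21740 and 22561 had a value on a given array. The lowest value on an array lay between 1.0 and 1.5. The number of arrays limits the precision. As a reference for background, 663 probes of olfactory receptor genes were used, a choice made after the data were examined. Their 95th percentile lay between 50.5 and 57.6 per array, with a geometric mean of 53.8, and between 40.1% and 42.4% of the measured probes exceeded it.

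Intensities were log2-transformed without a pseudocount. Column medians over measured probes were equal, so no further centring was applied; over the tested probes the array medians spanned 0.15 on the log2 scale. The 20434 probes with a value on all 6 arrays were tested, and 3032 probes were not. A linear model with 1 coefficient per genotype was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), because 2 arrays per genotype leave few residual degrees of freedom. The fit had 3 residual degrees of freedom and a prior worth 3.27. Contrasts were homozygous minus wild type, heterozygous minus wild type, homozygous minus heterozygous, and heterozygous minus the midpoint of the other genotypes, with a moderated F test over the 3 genotypes. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the probes tested, and the threshold was 0.05. Errors given after log2 fold changes are standard errors of the limma fit. They cover the spread between arrays and not the unknown background. Where both arrays of the lower genotype lay under their olfactory receptor 95th percentile, a bound of the fold was taken by setting them at that percentile, a step added after seeing the data. Each bound uses the geometric mean of the brighter arrays and makes no allowance for the spread between them.

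Gene symbols came from the platform's probe annotation: 16625 probes had 1 symbol, 0 had several and 6841 were unnamed here. Symbols were brought up to date through the synonyms of a mouse RefSeq gene table of assembly GRCm38.p6: 12620 were current, 3943 were replaced, 59 matched several genes and were kept, and 3 found no match and were kept. The table served only for names, chromosomes and neighbours. Of the tested probes, 14740 carried a symbol and stood for 14545 genes. Ecrg4 had 1 probe, listed under its older symbol.

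The genes named in the text followed a rule set before the data were examined. It took Ecrg4 and another gene that is not reported here, then for each pairwise comparison the 10 highest and 10 lowest log2 fold changes among probes past the threshold whose genotypes did not overlap, 1 probe per gene, leaving out predicted gene names. It added up to 4 passing members of each gene list that shifted, in the direction of the list, and up to 3 passing members of the others, and 5 genes per direction for the midpoint contrast. Genes outside the rule are marked where they appear. Gene lists, also set before the data were examined, were tested with camera at a preset correlation of 0.01, on the probe of highest mean per gene. The 27 lists with at least 5 measured genes were tested in 3 contrasts, and the 81 p-values were adjusted together. Camera with an estimated correlation and fry were run beside it. A p given with an estimated correlation is unadjusted unless it is called adjusted. A list of sex-linked genes held 1 measured member and was kept as values.

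The scripts were tested on simulated data. Of 20434 simulated probes, 200 were changed between homozygous and wild type. The fit recovered 94% of those changed by 3 log2 units, 74% of those changed by 2, 4% of those changed by 1 and 0% of those changed by 0.5, with 7 of 93 calls on unchanged probes. With no change simulated, 0 probes were called. A list shifted in the simulated homozygous arrays was called against wild type (adjusted p = 1.82e-10) and 0 of the other lists were. The simulated genes were independent of each other, so this cannot show how often a list of correlated genes is called without a shift. Overlaps of comparisons that share the wild-type arrays were set against 20 simulations of unchanged genotypes.

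Alternatives set before the data were examined were quantile, median and cyclic loess scaling, filters on dim probes, filling of blank cells, a pseudocount of 9.6, an intensity trend with a robust prior, array weights, fits on the compared arrays alone, a replicate block, averaging of a gene's probes, a linear allele term, other thresholds, and leaving out each array. A filter and a threshold at the olfactory receptor level, an intensity trend without the robust prior, and the median and loess scalings of the gene lists were added after seeing the data. Figures were drawn with matplotlib 3.10.9.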

Results

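The arrays measured transcript levels in cultured neonatal neural stem cells labelled Ecrg4 wild type, heterozygous or homozygous, with 2 arrays for each label. Arrays of 1 label correlated at r = 0.989 (wild type), 0.993 (heterozygous) and 0.994 (homozygous) across the 20434 tested probes, and probes are not independent replicates. The wild-type arrays were the most distant pair, with 4.05% of probes over 2-fold apart, against 2.40% for the heterozygous and 1.49% for the homozygous pair. Wild-type array 2 correlated with heterozygous array 1 at r = 0.990, above its correlation with wild-type array 1. On the first principal component, with 36.6% of the variance, the homozygous and heterozygous arrays lay at opposite ends and the wild-type arrays between them. The second component, with 30.9%, set wild-type array 1 apart. Of 24 measured stem and progenitor cell markers, 16 exceeded the 95th percentile of olfactory receptor probes on all 6 arrays and 6 lay below it on all 6, a count made after the data were seen. Among them, the radial glial lipid carrier Fabp7 read between 37400 and 46802 and the intermediate filament gene Vim between 17332 and 23739. Kdm5d, a Y-linked gene, read between 68.1 and 121.7 on the 6 arrays.

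Ecrg4 itself was examined first as a check of the labels. In the arrays labelled homozygous its probe read 1.4 and 1.3, next to the lowest values on those arrays, 1.2 and 1.0. It read 112.9 and 154.9 in the arrays labelled wild type and 345.5 and 373.9 in those labelled heterozygous. The measured values of Ecrg4 gave a log2 fold change of -6.62 ± 0.19 between homozygous and wild type (n = 2 arrays each, limma adjusted p = 0.000473) and of -8.06 ± 0.19 between homozygous and heterozygous (adjusted p = 0.000138). The homozygous values lay under the olfactory receptor 95th percentile, so the size of these changes depends on the background: with a pseudocount they were -3.70 and -5.07. With the homozygous arrays set at that percentile, Ecrg4 was at least 2.46-fold lower than in wild type and at least 6.68-fold lower than in heterozygous. Between the other labels it was 2.72-fold higher in heterozygous than in wild type (1.44 ± 0.19, 95% interval of the fold 1.96 to 3.76, adjusted p = 0.0395). The homozygous label matched the probe, but the order of the other 2 did not follow the number of unchanged alleles, so every direction below that involves them refers to the arrays as labelled. The part of the gene that the probe reads is not given in the sources used here. Leaving out wild-type array 1, either heterozygous array or either homozygous array ended the call between heterozygous and wild type, with adjusted p of 0.112 without wild-type array 1, 0.153 and 0.225 without heterozygous arrays 1 and 2, and 0.136 without either homozygous array. Filling blank cells (0.0689), array weights (0.0507) and a fit of only the arrays compared (0.136) ended it too. The last is the same fit as those without 1 homozygous array, whose remaining array adds nothing to the spread.

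**Figure D1:**
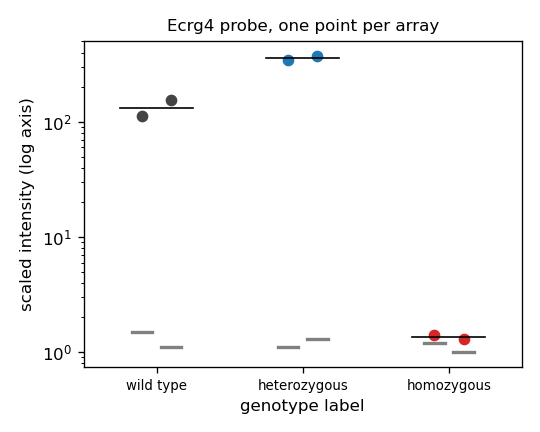
Scaled intensity of the Ecrg4 probe on a log axis against genotype label, with 1 point per array, black bars at the geometric mean of each pair and grey bars at the lowest value measured on each array. The homozygous arrays sit at 1.4 and 1.3, the wild-type arrays at 112.9 and 154.9 and the heterozygous arrays at 345.5 and 373.9.

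The comparison of arrays labelled homozygous with those labelled wild type asked what loss of the Ecrg4 transcript goes with in these cells. Sparcl1, a secreted matrix protein made by astrocytes, rose by 4.25 ± 0.28 on the log2 scale (limma adjusted p = 0.00583, n = 2 arrays each) and reached 1325 and 1301 from 55.9 and 85.0. Ddit4l, an inhibitor of mTOR signalling, rose by 4.70 ± 0.21, and the interferon-inducible GTPase gene Gbp7 and the fatty acid receptor gene Cd36 rose by 2.96 ± 0.20 and 2.45 ± 0.15. The neurexin ligand gene Nxph1 rose 5.65-fold. The smooth muscle actin gene Acta2 fell by 3.36 ± 0.22, and so did the tetraspanin gene Cd82 (-3.95 ± 0.41), the zinc finger gene Zfp280b (-4.36 ± 0.30) and the G protein subunit gene Gng2 (-2.83 ± 0.19). In all, 188 of 20434 probes changed, 88 higher and 100 lower, covering 63 and 76 named genes; without wild-type array 2 the split was 169 higher and 55 lower, and with median centring it was 126 and 188. For 15 of 36 named genes 1 of the genotypes lay under the olfactory receptor level. For 12 of these a bound of the change is measured, such as at least 3.44-fold for Ddit4l, 2.28-fold for Cd82 and 1.12-fold for Gng2. For 3, Abhd1, Emx2 and Ndrg1, no bound above 1 could be given. For 10 more both genotypes lay under that level.

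Other genes that rose most were Tmem37 (3.04 ± 0.38), the protease-activated receptor gene F2rl2 (2.80 ± 0.35), the actin-binding protein gene Tagln2 (2.72 ± 0.39), Brinp1 (2.62 ± 0.26) and Abhd1 (2.44 ± 0.28). The X-linked gene Xlr3b, which has near-identical copies that its probe may not separate, gave -2.87 ± 0.28. Among the remaining large decreases, the actin-oxidising enzyme gene Mical1 gave -2.94 ± 0.23, Vit -2.89 ± 0.28, the neuropeptide receptor component Ramp1 -2.78 ± 0.30 and Calml4 -2.76 ± 0.40. Brinp1, F2rl2, Mical1 and Calml4 stayed below the olfactory receptor 95th percentile on every array, and such probes are called dim. With the wild-type arrays set at that percentile, Tmem37 was at least 1.11-fold higher, and for Abhd1 no such bound could be given.

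The glycolysis and hypoxia genes were lower as a group in the arrays labelled homozygous. Their median log2 fold change against wild type was -0.84 over 29 genes, 26 of them below 0 (camera adjusted p = 5.12e-08), but the p with an estimated correlation of 0.61 was 0.204. Across all probes 1 member fell, the hypoxia-inducible Ndrg1 (-2.15 ± 0.20), and adjusted over the list alone 19 fell and 2 rose. Members that did not pass across all probes, chosen after their values were seen, included the lactate exporter Slc16a3 (-1.78 ± 0.36), the pyruvate dehydrogenase kinase Pdk1 (-1.57 ± 0.44) and, with the opposite sign, the peptide hormone gene Adm (1.39 ± 0.27). Without wild-type array 2 the median was -0.54, still past the threshold. The list's mean was -0.12 and 0.57 in the wild-type arrays, 0.26 and 0.43 in the heterozygous and -0.41 and -0.73 in the homozygous, relative to each gene's mean.

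**Figure D2:**
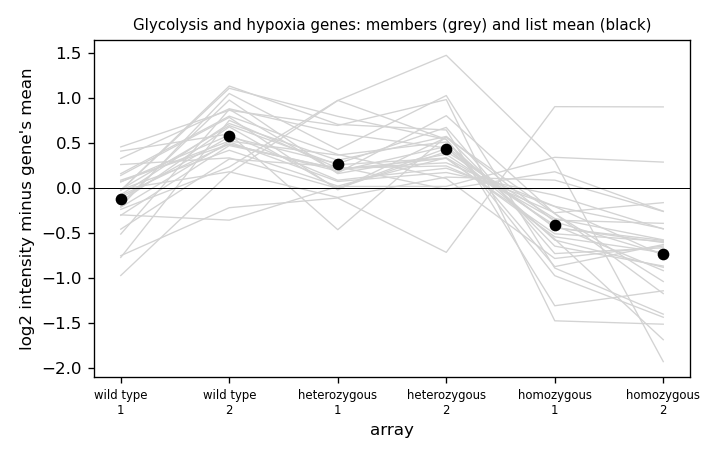
Log2 intensity minus each gene's own mean for 29 glycolysis and hypoxia genes on the 6 arrays, with 1 grey line per gene and black points at the list mean of each array. The list means are -0.41 and -0.73 in the homozygous arrays, and the wild-type arrays lie apart at -0.12 and 0.57.

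Neuronal genes moved upward in single members: the growth cone gene Gap43 (1.44 ± 0.19), the RNA-binding protein gene Elavl4 (1.40 ± 0.19) and the neurofilament gene Ina (0.98 ± 0.14) rose, 3 of 20 measured neuron markers, or 4 adjusted over the list alone, while the list itself did not pass (camera adjusted p = 0.0696, p = 0.0899 with an estimated correlation). Of 20 measured forebrain factors the patterning gene Emx2 (1.55 ± 0.16) rose and Nr2f2 (-1.43 ± 0.15) fell, also 1 and 1 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.855). Of 22 hindbrain and spinal cord factors the Iroquois gene Irx1 (-2.16 ± 0.16) fell, and adjusted over the list alone 3 fell, with no call for the list (camera adjusted p = 0.192). The laminin gene Lamb2 fell by 1.49 ± 0.16, and the sterol reductase gene Tm7sf2 fell as well (-1.02 ± 0.14). Of 25 measured Notch, BMP and TGF-beta targets, Tgfbi (-2.59 ± 0.34) and Msx1 (-1.30 ± 0.19) fell, and adjusted over the list alone 3 fell. Among genes of senescent cell secretion Igfbp4 (1.94 ± 0.16) and the chemokine gene Cxcl10 (1.51 ± 0.18) were higher, 2 of 21 measured members, and adjusted over the list alone 3 rose and 3 fell. Ifit2 (1.18 ± 0.15), P2ry12 (1.98 ± 0.22) and Cd14 (1.23 ± 0.17) also rose, on dim probes like those of Tgfbi, Msx1 and Cxcl10. The count of 188 was 1094 with an intensity trend and robust prior and 59 with only the arrays compared. It was 45 without wild-type array 1, 59 without either heterozygous array and 1 without either homozygous array.

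The arrays labelled heterozygous were compared with those labelled wild type for the effect of 1 changed allele. Scg5, a chaperone of a prohormone convertase, rose by 4.70 ± 0.29 on the log2 scale (limma adjusted p = 0.00368, n = 2 arrays each), from 4.4 and 5.2 to 118.0 and 131.5. The protease inhibitor gene Timp1 rose by 3.32 ± 0.31, Ilvbl by 3.23 ± 0.17 and the lysosomal protease gene Ctsc by 3.02 ± 0.16. Xlr3b fell from 1192 and 1254 to 10.4 and 6.2 (-7.25 ± 0.28), and Zcchc12 (-3.87 ± 0.21) and the monoamine oxidase gene Maoa (-2.99 ± 0.28) fell. In all, 153 probes changed, 84 higher and 69 lower; without wild-type array 2 the split was 267 higher and 73 lower, and without heterozygous array 1 it was 19 and 24. For 15 of 31 named genes 1 genotype lay under the olfactory receptor level, and for 14 of these a bound is measured: the change was at least 2.25-fold for Scg5, 6.71-fold for Timp1, 4.24-fold for Ilvbl and 23.4-fold for Xlr3b. For 10 genes both genotypes lay under it. Over the alternatives the log2 fold change of Scg5 ranged from 3.22 to 4.82 and that of Xlr3b from -7.62 to -6.12.

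Further genes that rose were Ddit4l (3.02 ± 0.21), Slc7a4 (2.93 ± 0.20), Mamdc2 (2.84 ± 0.17), Rmdn2 (2.78 ± 0.19) and the peroxisomal enzyme gene Phyh (2.77 ± 0.21). Their wild-type arrays lay under the olfactory receptor level. The bounds were at least 1.08-fold for Ddit4l, 1.14-fold for Slc7a4, 1.85-fold for Mamdc2, 1.05-fold for Rmdn2 and 3.50-fold for Phyh. For Rmdn2, heterozygous array 1, at 52.5, lay under its own level of 54.2. A probe listed for alpha-tubulin Tuba1b rose by 3.09 ± 0.26, but related tubulin transcripts may share it. Zfp280b (-4.69 ± 0.30) and Ramp1 (-4.12 ± 0.30) fell here as well. On dim probes, decreases were measured for the serotonin receptor gene Htr5b (-3.17 ± 0.40), the synaptic protein gene Lrfn2 (-2.94 ± 0.30), the retinoid receptor gene Rxrg (-2.60 ± 0.27) and Sdr42e1 (-2.49 ± 0.28). The synaptic protein gene Nptx2 (-2.73 ± 0.30) fell too, with both genotypes under the olfactory receptor level. Also on dim probes, the forebrain homeobox genes Dlx1 (-2.04 ± 0.20) and Dlx2 (-1.15 ± 0.14) were lower, 2 of 20 measured members of their list, and adjusted over the list alone 2 fell and 1 rose. Hoxa5, a homeobox gene of the posterior nervous system, was higher by 2.31 ± 0.29, but no bound above 1 could be given for it. Acta2 was lower by 1.90 ± 0.22. Gap43 (1.32 ± 0.19) and Igfbp4 (1.57 ± 0.16) rose, Ina fell and was at least 1.30-fold lower, the myelin lipid enzyme gene Ugt8a fell too (-1.67 ± 0.23), and of the dim microglial genes Cd14 rose by 1.57 ± 0.17 and Cx3cr1 gave -1.30 ± 0.17.

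No gene list passed between heterozygous and wild type with camera. The nearest was the astrocyte list, with a median of 0.33 over 20 genes and an adjusted p of 0.0575, and a p of 0.357 with an estimated correlation. None of its members passed across all probes, and adjusted over the list alone 6 rose and 1 fell. Scg5, Ilvbl, Ctsc, Mamdc2, Xlr3b, Zcchc12 and Zfp280b passed under every alternative in which they were tested. The count of 153 was 400 with an intensity trend and robust prior and 40 with only the arrays compared. It was 33 without wild-type array 1 and 340 without wild-type array 2, 43 and 18 without heterozygous arrays 1 and 2, and 40 without either homozygous array.

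Between the arrays labelled homozygous and those labelled heterozygous 549 probes changed, 257 higher and 292 lower; without heterozygous array 1 the split was 46 higher and 34 lower, and with blank cells filled it was 168 and 167. With median centring it was 308 and 475, with cyclic loess 296 and 440, over 2-fold above the olfactory receptor level 91 and 167, and without homozygous arrays 1 and 2 it was 0 and 7 and 0 and 6. At an unadjusted p under 0.05 there were 3710, against 3887 between homozygous and wild type. Gng2 fell by 5.09 ± 0.19 on the log2 scale (limma adjusted p = 0.000927, n = 2 arrays each). Scg5 (-5.62 ± 0.29), Ilvbl (-4.42 ± 0.17), the sarcomere protein gene Pdlim3 (-4.16 ± 0.30) and the adhesion molecule gene Chl1 (-3.91 ± 0.19) fell as well. Xlr3b (4.38 ± 0.28), Zcchc12 (3.54 ± 0.21), Nxph1 (2.99 ± 0.18) and Sparcl1 (3.04 ± 0.28) rose, as did Dmrta2, a transcription factor of cortical progenitors (3.26 ± 0.21). Hoxa5 (-3.84 ± 0.29), Timp1 (-3.75 ± 0.31), Calml4 (-3.91 ± 0.40) and Cd82 (-3.54 ± 0.41) were lower, and Cadps (3.82 ± 0.28), Nptx2 (3.72 ± 0.30), Lrfn2 (3.42 ± 0.30), Brinp1 (3.25 ± 0.26) and Tmem37 (2.86 ± 0.38) were higher. For 20 of 52 named genes 1 genotype lay under the olfactory receptor level, and for 18 of these a bound is measured: the decrease was at least 5.37-fold for Gng2, 2.31-fold for Scg5, 4.35-fold for Ilvbl and 2.84-fold for Pdlim3. By geometric means Nptx2 was at least 1.003-fold higher, but homozygous array 1, at 47.6, lay under its own level of 51.3. For Hoxa5 no bound above 1 could be given. For another 18 genes both genotypes lay under the olfactory receptor level. The log2 fold change of Scg5 ranged from -6.03 to -3.46 over the alternatives.

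Here 3 gene lists passed with camera. The glycolysis and hypoxia genes had a median of -0.92, with 27 of 29 genes below 0 (adjusted p = 5.27e-09; the p with an estimated correlation was 0.180). Ndrg1 (-2.33 ± 0.20), the Myc antagonist Mxi1 (-1.51 ± 0.24) and the glycolytic enzyme gene Tpi1 (-1.17 ± 0.21) fell, and adjusted over the list alone 14 fell and 1 rose. The mitosis genes had a median of -0.14, with 25 of 31 genes below 0 (adjusted p = 0.0210; p = 0.182 with an estimated correlation), and the median was -0.29 without homozygous array 2. Of these the cyclin gene Ccnb2 fell by 1.11 ± 0.17, and adjusted over the list alone 3 fell. The neuron markers had a median of 0.23, with 4 of 20 genes below 0 (camera adjusted p = 0.0455). With an estimated correlation the list's unadjusted camera p was 0.0707 and its adjusted p was 0.951. The median was 0.12 without homozygous array 1 and 0.38 without heterozygous array 2. In this list 15 of 20 genes were dim, and 4 exceeded the olfactory receptor 95th percentile on every array. The median and the sign count of the neuron list thus rest mostly on probes under that level. Ina (1.97 ± 0.14), the secretory granule gene Scg2 (1.96 ± 0.27) and Elavl4 (1.27 ± 0.19) rose, and adjusted over the list alone 4 rose. Quantile and cyclic loess scaling ended the call of the mitosis list, with a median of -0.09 in both (adjusted p = 0.162 and 0.173). They also ended the call of the neuron list, whose median was 0.23 and 0.21 (adjusted p = 0.146 and 0.115). The mitosis call also ended without heterozygous array 2 (0.140) or homozygous array 1 (0.0999), and the neuron call without wild-type array 1 (0.0789) or 2 (0.118), heterozygous array 1 (0.0750) or homozygous array 1 (0.105).

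Members of other lists also differed between these labels. The astrocyte water channel gene Aqp4 (-2.37 ± 0.37) and Ndrg2 (-2.42 ± 0.44) fell while Sparcl1 rose, 3 of 20 astrocyte markers, and adjusted over the list alone 7 fell and 2 rose. Dlx1 (1.83 ± 0.20), Dlx2 (1.47 ± 0.14) and Emx2 (1.09 ± 0.16) rose and Nr2f2 (-1.07 ± 0.15), named after its value was seen, fell, 3 and 1 of 20 forebrain factors, and adjusted over the list alone 4 rose and 1 fell. Irx1 (-2.36 ± 0.16), Hoxa2 (-1.15 ± 0.19) and Irx5 (-0.998 ± 0.145), the last named after its value was seen, fell with Hoxa5, 4 of 22 hindbrain and spinal cord factors and also 4 adjusted over the list alone. The oligodendrocyte lineage genes Ugt8a (1.80 ± 0.23) and Bcas1 (1.51 ± 0.22) rose, 2 of 18 measured members and also 2 adjusted over the list alone. The receptor gene Notch1 (-0.81 ± 0.14), Tgfbi (-3.54 ± 0.34), Pmepa1 (-1.23 ± 0.18), Lamb2 (-1.52 ± 0.16), Lama4 (-1.38 ± 0.23), Acta2 (-1.46 ± 0.22), Col6a1 (-1.91 ± 0.22) and Foxc1 (-0.99 ± 0.17) fell. The chemokine genes Ccl2 (1.28 ± 0.20) and Cxcl10 (1.42 ± 0.18) rose, together with Lama1 (1.01 ± 0.15), Ifit2 (1.81 ± 0.15), P2ry12 (1.62 ± 0.22) and Cdon (1.36 ± 0.23). The probes of Calml4, Brinp1, Lrfn2, Cadps, Scg2, Tgfbi, Lama4, Col6a1, Foxc1, Cxcl10, Lama1, Ifit2, P2ry12, Cdon, Dlx1, Dlx2, Hoxa2 and Ugt8a were dim. By geometric means Aqp4 was at least 1.02-fold lower, but heterozygous array 2, at 45.5, lay under its own level of 50.5. For Emx2 no bound above 1 could be given. Of 34 measured members of the list of genes near Ecrg4, Tbc1d8 (0.98 ± 0.16) rose and Col5a2 (-0.97 ± 0.14) fell. Gulp1, within 5 Mb of Ecrg4 but not on that list, gave -1.68 on a dim probe and was named after its value was seen. The count of 549 was 1357 with an intensity trend and robust prior. It was 80 and 72 without heterozygous arrays 1 and 2, and 7 and 6 without homozygous arrays 1 and 2.

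**Figure D3:**
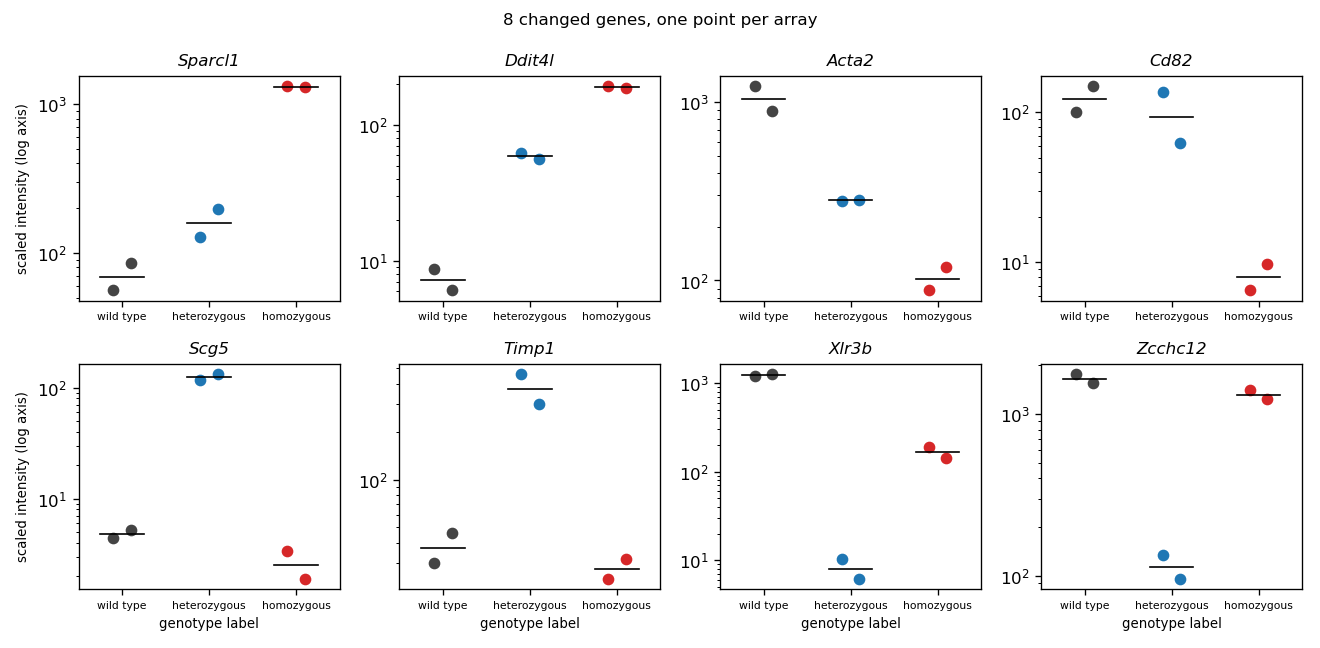
Scaled intensity on log axes of 8 genes against genotype label, with 1 point per array and a bar at the geometric mean of each pair. Sparcl1 reaches 1325 and 1301 in the homozygous arrays, and Xlr3b drops to 10.4 and 6.2 in the heterozygous arrays.

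In a test of whether the arrays labelled heterozygous lay midway between the others, 313 probes departed from the midpoint, 166 above and 147 below. Scg5 lay 5.16 ± 0.25 above it, Ecrg4 4.75 ± 0.17, Ilvbl 3.82 ± 0.15, Gng2 3.67 ± 0.16 and Timp1 3.54 ± 0.27. Xlr3b (-5.81 ± 0.24), Zcchc12 (-3.70 ± 0.18), Nptx2 (-3.22 ± 0.26), Lrfn2 (-3.18 ± 0.26) and Maoa (-2.90 ± 0.24) lay below it. Except for Zcchc12 and Maoa, these distances rest in part on values under the olfactory receptor level, and over the alternatives that of Scg5 ranged from 3.34 to 5.37 and that of Ecrg4 from 3.23 to 4.86. By the F test 462 probes differed among the 3 genotypes. Wild type was in the middle for 234 of them (50.6%), heterozygous for 120 (26.0%) and homozygous for 108 (23.4%), where no order among genotypes would give 33.3% each. The shares in the same order were 40.6%, 27.8% and 31.7% without wild-type array 2. Without homozygous arrays 1 and 2 the order differed: homozygous was in the middle for 54.2% and 44.0%, wild type for 33.3% and 40% and heterozygous for 12.5% and 16% of the 24 and 25 probes. The count of 313 was 820 with an intensity trend and robust prior. Without heterozygous arrays 1 and 2 it was 30 and 18, without homozygous arrays 1 and 2 it was 55 and 38, and without wild-type array 2 it was 530, 363 above and 167 below; the F count in these fits, in the same order, was 111, 87, 24, 25 and 843.

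**Figure D4:**
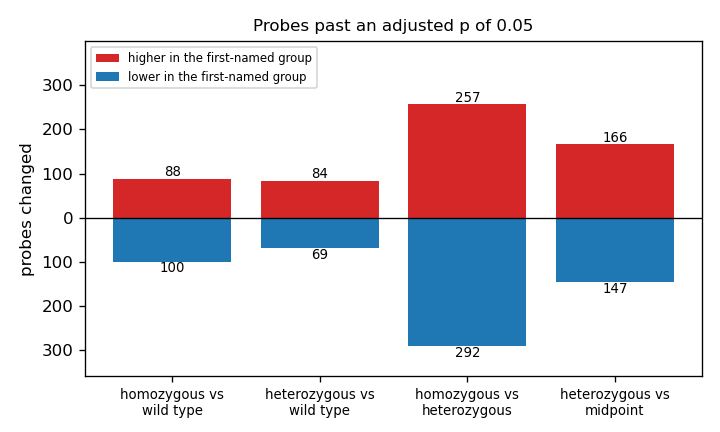
Number of probes past the threshold in each contrast, drawn upward for probes higher and downward for probes lower in the genotype named first. The homozygous against heterozygous contrast has 257 higher and 292 lower.

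The changes against wild type overlapped. Of 45 probes called in both comparisons, 26 were higher in both and 13 lower in both, against 0.362 and 0.338 for independent lists, which leave out the shared wild-type arrays. The mean in simulations of unchanged genotypes was 0, but with no change simulated hardly any calls can arise, so this does not measure what the shared arrays add to the overlap. Ddit4l rose and Zfp280b, Ramp1, Acta2 and Xlr3b fell in both, whereas Ecrg4, Gng2, Ilvbl and Ina were called in opposite directions. The log2 fold changes correlated at r = 0.402 across probes, against 0.494 in the simulations, and their covariance was 0.0773 against 0.0461. The simulations gave every array of a probe the same spread, whereas the shared wild-type arrays were the most distant pair. They had 4.05% of probes over 2-fold apart, against 2.40% for the heterozygous and 1.49% for the homozygous pair. The simulated covariance may thus be too low, and the gap does not show a change common to both genotypes. Part of the overlap may come from the shared arrays. The 39 probes called in the same direction were 99 without wild-type array 2, 10 without wild-type array 1, 12 and 9 without heterozygous arrays 1 and 2, and 0 without either homozygous array.

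The other 24 gene lists did not pass in any pairwise comparison, and each is given by its smallest camera adjusted p. It was 0.0574 for ribosomal proteins, 0.0575 for astrocyte markers, 0.0903 for fibroblast and meningeal markers, 0.112 for the respiratory chain, 0.141 for microglia, 0.180 both for endothelial and pericyte markers and for growth factor and MAPK targets, and 0.192 for hindbrain and spinal cord factors. For oligodendrocyte markers it was 0.212, for Notch, BMP and TGF-beta targets 0.241, for DNA replication 0.287, for Wnt and Hedgehog targets 0.304, for forebrain factors and cholesterol synthesis 0.318 each, for CDK inhibitors and p53 targets 0.327, for genes near Ecrg4 0.381 and for matrix and adhesion genes 0.382. Stem cell markers gave 0.547, senescent cell secretion 0.606, interferon response 0.639, protein and amino acid stress 0.668, antigen presentation 0.682, ependymal markers 0.702 and heat shock 0.845. With an estimated correlation 0 of 81 camera tests passed, the smallest unadjusted p being 0.0707 and the smallest adjusted p 0.951. Fry called 0 directional shifts (smallest adjusted p 0.204). Its test for members changed in any mix of directions passed 62 times, which does not show that a list shifted. The median, the mean and the camera direction differed in sign in 13 of the 81 tests and in 0 of the called ones.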

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

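The filter and threshold at the olfactory receptor level, the intensity trend without a robust prior and the loess and median scalings of gene lists were chosen after the results were seen. Of 126 results for named genes, 0 reversed under any alternative run; over 2796 values 2144 kept their side of the threshold and 652 did not, 400 of them among the 756 values with 1 array left out. Counting Ecrg4, 18 of 129 results, on 10 genes, passed in every setting that gave a value, among them Scg5, Ilvbl, Xlr3b and Zcchc12 between heterozygous and wild type and Chl1 and Gng2 between homozygous and heterozygous. The absence of reversals was close to fixed in advance, because the named genes were chosen as past the threshold in these data. Other thresholds and the replicate block also leave the log2 fold change itself unchanged. The causes of the changes in counts below were not tested, except that fits with 1 array fewer have fewer samples.

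Counts are given for homozygous against wild type, heterozygous against wild type, homozygous against heterozygous, the midpoint contrast and the F test, in that order, against 188, 153, 549, 313 and 462; a count within 1.5 times of these is left out. An adjusted p under 0.1 gave 662, 273, 1121, 662 and 1112. A pseudocount gave 1135, 398, 1427, 818 and 1616. An intensity trend with a robust prior gave 1094, 400, 1357, 820 and 1582, and without it 984, 370, 1310, 759 and 1442. Leaving out probes under the 25th percentile gave 671, 255, 983, 548 and 974. Leaving out those under the median gave 789, 898 and 938 for the first, the third and the F test. Leaving out those under the olfactory receptor level gave 877, 1016, 498 and 1069, all but the second. Changes over 2-fold above that level numbered 120, 85, 258 and 140 in the first 4. Filling blank cells with the lowest value gave 87, 335 and 267 for the first, the third and the F test. Array weights gave 89, 100, 1261 and 791, all but the midpoint. Only the arrays compared gave 59 and 40 against wild type. For homozygous against wild type, quantile scaling gave 328, median centring 314, cyclic loess 313 and a linear term in allele number 5; centring gave 721 by the F test.

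Ecrg4 kept its difference of 1.44 between heterozygous and wild type with blank cells filled, with array weights and with only the arrays compared, but not the call (adjusted p = 0.0689, 0.0507 and 0.136); over its alternatives the adjusted p ranged from 0.00266 to 0.225. In the linear term its difference of -6.62 did not pass. Of 4 gene list shifts, 2 were called under quantile scaling, 2 under cyclic loess and 0 with an estimated correlation. The adjusted p of the mitosis list and of the neuron list between homozygous and heterozygous each ranged from 0.00277 to 0.951 over the alternatives.

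Whether arrays of equal number in different genotypes share more than that number is not given in the sources used here. Their deviations from the genotype means correlated at 0.0156, 0.00999 and -0.0759, which cannot settle it. With the replicate number as a block, the counts were 47, 51, 244, 142 and 166, the overlap was 13 probes, and the Ecrg4 difference of 1.44 did not pass (adjusted p = 0.0860).

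With each array left out in turn, the remaining array of its genotype was assumed to vary like the others. For the comparison of the other genotypes, such a fit equals that of only the arrays compared and is not a separate alternative. The counts then ranged from 1 to 224, from 18 to 340, from 6 to 680, from 18 to 530 and from 24 to 843. The overlap ranged from 0 to 99 probes, the correlation of changes against wild type from 0.342 to 0.604, and the called list shifts from 3 to 9. The Ecrg4 difference ranged from 1.21 to 1.67 between heterozygous and wild type, from -6.84 to -6.39 between homozygous and wild type and from -8.11 to -8.00 between homozygous and heterozygous. The glycolysis and hypoxia list passed in each of these fits, with a median between -1.14 and -0.54 against wild type and between -0.98 and -0.76 against heterozygous. Signal over background limits the dim probes: between 40.1% and 42.4% of measured probes exceeded the olfactory receptor level.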

Other observations

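The values of the first paragraph were picked after they were seen, as were the tests of other transcripts, of exchanged labels at the Ecrg4 locus, of Ecrg4 under other scalings, of allele number, of imprinted genes and of chromosomes. Probes that passed against wild type in opposite directions numbered 6 and included 1 of 2 probes of Zfhx3, a transcription factor gene, at 16.4 and 16.9 in wild type, 41.4 and 39.1 in heterozygous and 6.4 and 7.4 in homozygous. Chl1 read 29.8 and 33.1, 126 and 160.8, and 8.7 and 10.3 in the same order, and the other 4 were Ecrg4, Ilvbl, Gng2 and Ina. Mest, an imprinted gene expressed from the paternal allele, differed among the genotypes by the F test (limma adjusted p = 0.00398). It read 1381 and 1493 in wild type, 415.4 and 363.5 in heterozygous and 2484 and 2600 in homozygous. The imprinted gene Ndn read 161.7 and 191.4, 284 and 269.7, and 111.2 and 103.1 (adjusted p = 0.0269). Pax7, a dorsal patterning gene, had no value in either heterozygous array and a mean intensity of 17.4 in homozygous, below the olfactory receptor 95th percentile. Probes measured on both homozygous arrays and blank on both heterozygous arrays numbered 207, and 0 of these exceeded that level.

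Ecrg4 was higher in the arrays labelled heterozygous than in those labelled wild type. Array scaling is argued against, since the lowest difference under the other scalings was 1.39 on the log2 scale. Another transcript read by the probe stays open. The homozygous mean was 0.598% of the gap, which limits only a transcript that is also present in the homozygous arrays. A transcript read alike in every genotype would cancel in the gap, so this value cannot test it. Exchanged wild-type and heterozygous labels stay open: of 32 genes within 5 Mb of Ecrg4, 2 differed among genotypes, Gulp1 with wild type and Tbc1d8 with heterozygous in the middle (exact binomial p = 1), too few to decide. A biological effect of 1 changed allele on the remaining transcript may also account for it and was not tested.

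Wild type lay between the other genotypes more often than heterozygous did. Scaling is argued against, as the share with wild type in the middle was at least 51.2% under the other scalings. The share depended on single arrays, however: it was 40.6% without wild-type array 2, and 33.3% and 40% without homozygous arrays 1 and 2. An effect that grows with the number of changed alleles, as labelled, cannot be told apart from the alternatives. In fits without 1 array the share with heterozygous in the middle reached at most 31.0%, under the 33.3% of no order. With a 95% binomial interval around each share, this does not decide. Among probes above the olfactory receptor level the share was 37.0%, but wild type was in the middle for 47.5% of them. Exchanged labels with such a stepwise effect may also fit in part. The share of wild-type-middle probes in the central part of the gap was 61.1%, and it was as low as 40% without homozygous array 2, which decides neither way.

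Glycolysis and hypoxia genes were lower in the arrays labelled homozygous. Scaling is argued against, since the list's median stayed at -0.84 or below under the other scalings. A culture state that varies between single arrays, such as oxygen or cell density, may account for it and cannot be told apart from genotype: the wild-type arrays differed by 0.69 in the list's mean, which was 86.9% of the gap between wild type and homozygous. With 2 arrays per genotype, a biological effect of genotype stays open too.

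The hypothesis that imprinted genes change more often than others was left open. Of 54 measured imprinted genes 4 differed among genotypes (Mest, Ndn, Xlr3b and Xlr4b), against a median of 1 in 10000 random lists matched on intensity, a count at the 94.5th percentile. Xlr3b and Xlr4b were both lowest in heterozygous, and lists matched on intensity do not allow for genes that move together. The hypothesis of a gained or lost chromosome copy was not borne out for any autosome, as the largest median difference, on chromosome 18, was 0.0873 on the log2 scale. The X chromosome was left out of that test. Its median was 0.126 for heterozygous minus wild type, -0.113 for homozygous minus heterozygous and 0.00894 for homozygous minus wild type.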
